A study of Homo sapiens with 12 samples.

How the data were processed

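Total RNA from the human acute myeloid leukaemia line THP-1, grown in RPMI1640 with 10% serum per the labels, was profiled in 12 libraries. The sample titles give 4 groups of 3: KLF4 overexpression and its controls, NRBP2 overexpression and its controls. Nothing in the labels states that replicates were separate cultures, so the p values measure only the spread between these samples, which may be technical. The deposited table holds raw read counts per Ensembl gene, which the authors made by alignment and read counting, with STAR 2.7.10b, SAMtools 1.16 and HTSeq 2.0.2 named per the submitters' processing notes. Those notes name the builds mm10 and hg38 side by side. The values are whole numbers for 58735 genes, and no column belongs to any other sample. All 58735 gene identifiers occur in GENCODE release 29, and 58653 have the same GRCh38 coordinates. Strand setting, handling of reads that match several genes and annotation release are not given in the sources used here, so reads over overlapping genes and near-identical copies are uncertain.

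Library totals ran from 28180790 to 37330882 counts. A floor of 3 counts equals 0.0804 to 0.1065 CPM in a library, and 3 counts summed over a group equal 0.0312 CPM (KLF4 controls), 0.039 (KLF4 overexpression), 0.0307 (NRBP2 controls) and 0.027 (NRBP2 overexpression). A gene with 0 counts in a group is given as at least N-fold from the group floor. Counts in genes of protein-coding type made up 97.35% to 97.78% of each library. Within groups the correlation of log2 CPM was 0.986 to 0.990, and the chi-square per degree of freedom between replicate pairs was 3.796 to 16.569, so no library duplicates another.

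Genes were kept by edgeR's filterByExpr over the 4 groups (19006 genes), scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3, as quasi-likelihood models with robust dispersion and 1 mean per group over all 12 libraries (8 residual degrees of freedom, median prior degrees of freedom 15.2, common biological coefficient of variation 7.7%). The fits assume that the 4 groups vary alike. The comparisons were KLF4 overexpression minus its controls, NRBP2 overexpression minus its controls, the difference between these effects, and NRBP2 controls minus KLF4 controls. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is the unshrunk coefficient divided by the root of F. Fold changes in the text are ratios of mean CPM, and log CPM used a prior count of 2. KLF4, NRBP2 and KMT2C also had a two-sided exact permutation test of log2 CPM.

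Lists of 30 gene groups (887 symbols, 883 matched) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Members were counted as higher or lower after adjustment over all genes, and adjusted over the list alone. The shared genes of the KLF4 and NRBP2 effects were tested with Fisher's exact test in each direction, which takes genes as independent. Groups, comparisons, lists, naming rule and alternatives were chosen before the data were examined, apart from those said to be added. Named genes are KLF4, NRBP2 and KMT2C, then up to 8 protein-coding genes per direction with the largest log2 change among those past the threshold, at a mean of 5 CPM or more and with all libraries of 1 side beyond those of the other. Up to 2 members per direction with the smallest p were named from each list, up to 5 genes per direction from the shared genes, the difference and the controls, and up to 3 per opposite direction. Some list members that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

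Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library size alone, no low-count filter, 1 CPM in 6 libraries, a 2-fold threshold, the 6 compared libraries alone, replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Added after the data were examined were the controls of the other experiment and counts without the genes near 0 in the KLF4 controls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with a seed of 20.

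The gene fits and the camera test were tried on simulated data with 17729 genes. For KLF4, 80.6% of genes simulated at 1.5-fold, 80.6% at 2-fold and 100% at 4-fold were recovered, with 8 false calls among 211 calls, members of a shifted mitosis list included (3.8%). For NRBP2 the shares were 62.7%, 89.6% and 100%, with 13 false calls among 181 (7.2%). A mitosis list shifted 1.3-fold was called, and 0 of the other 28 lists were. In each comparison 67 genes changed at 1.5-fold, 67 at 2-fold and 66 at 4-fold, and genes were drawn independently. The simulation therefore does not test the scaling where most genes change, nor the list test where members of a list are correlated.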

Results

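THP-1 is a human monocytic cell line established from an acute myeloid leukaemia that carries an MLL (KMT2A) fusion. Total RNA was sequenced from 12 THP-1 libraries in 4 groups of 3: cells overexpressing KLF4, a zinc-finger transcription factor of the monocyte lineage, cells overexpressing NRBP2, a pseudokinase, and a separate set of controls for each. The labels set the 2 genes beside MLL3, the histone methyltransferase encoded by KMT2C, in an axis in which KLF4 raises NRBP2 transcription. The comparisons therefore ask what each overexpression changed, whether NRBP2 and KMT2C transcripts moved with KLF4, and whether KLF4 and NRBP2 moved the same genes. The libraries held between 28180790 and 37330882 gene counts, with group means of 30.52 ± 0.36 M (KLF4 controls), 29.52 ± 1.2 M (KLF4 overexpression), 31.15 ± 1.06 M (NRBP2 controls) and 35.41 ± 1.68 M (NRBP2 overexpression). At these depths 3 counts in a library correspond to 0.0804 to 0.1065 CPM by library size, and CPM of genes below are TMM-normalized. All errors on CPM are SD over n = 3 libraries, and adjusted p values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19006 genes.

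The overexpressed genes followed their labels in each library. KLF4 (ENSG00000136826, chromosome 9, 107484852 to 107490482, GRCh38) stood at 91.8 ± 4.14 CPM in its controls and at 5141 ± 291 CPM with KLF4 overexpression, 56.0-fold higher. NRBP2 (ENSG00000185189, chromosome 8, 143833594 to 143840974) stood at 12.1 ± 0.707 CPM in its controls and at 4518 ± 302 CPM with NRBP2 overexpression, 373-fold higher. The counts do not separate transcripts of a construct from those of the endogenous gene.

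With KLF4 overexpression, NRBP2 rose 28.0-fold, from 13.2 ± 1.19 to 368 ± 15.8 CPM, a log2 fold change of 4.81 (SE 0.066, edgeR adjusted p = 4.6e-26). KMT2C (ENSG00000055609, chromosome 7, 152134922 to 152436005) rose 1.58-fold, from 142 ± 5.52 to 223 ± 4.39 CPM (log2 0.66, SE 0.052, edgeR adjusted p = 2.9e-11). With library size alone as the scaling, log2 changes in this comparison shifted by a median of -0.272, so the size of the KMT2C rise depends on the scaling. Over 15 alternatives its adjusted p ranged from 1.13e-45 to 3.74e-07. With NRBP2 overexpression neither partner passed the threshold against its own controls. KLF4 stood at 17.7 ± 2.14 CPM in the NRBP2 controls and at 16 ± 0.844 CPM in the overexpressing cells (log2 -0.14, edgeR adjusted p = 0.16), and KMT2C at 112 ± 5.55 and 104 ± 4.0 CPM (log2 -0.11, edgeR adjusted p = 0.13). Without replicate 3 of the NRBP2 controls the KLF4 value became -0.24 and passed (edgeR adjusted p = 0.00773), while over 15 alternatives its adjusted p ranged from 1.88e-18 to 0.596. KLF4 was 5.19-fold lower in the NRBP2 controls than in the KLF4 controls (log2 -2.38, edgeR adjusted p = 5.1e-19), so that NRBP2 overexpression set against the KLF4 controls gave a KLF4 value of -2.52. KMT2C passed against the KLF4 controls (log2 -0.44, edgeR adjusted p = 5.0e-07), in a range over alternatives of 5.03e-07 to 0.414. In the two-sided exact permutation test of log2 CPM the 3 libraries of each side were fully separated for KLF4, NRBP2 and KMT2C with KLF4 overexpression and for NRBP2 and KMT2C with NRBP2 overexpression, each at p = 0.1, the smallest that 3 against 3 can give. KLF4 with NRBP2 overexpression gave an exact p = 0.4.

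**Figure D1:**
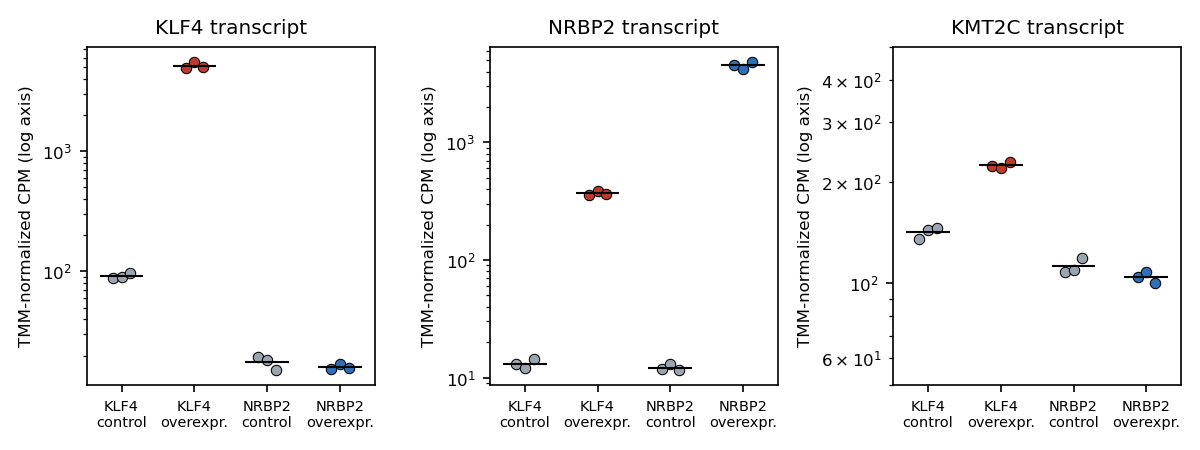
KLF4, NRBP2 and KMT2C transcripts in each of the 12 libraries, as TMM-normalized CPM on a log axis, with points for libraries and a line for each group's mean. NRBP2 lies between 358 and 386.4 CPM in the 3 KLF4 overexpression libraries and between 11.67 and 14.42 CPM in the 6 control libraries, and KLF4 is higher in its own controls (88.64 to 96.45 CPM) than in the 6 libraries of the NRBP2 experiment (15.26 to 19.34 CPM).

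KLF4 overexpression lowered the genes of cell division and of DNA replication together and raised lysosomal and interferon-stimulated genes. All 35 genes of the G2/M and mitosis list fell, with a median log2 change of -2.38. MKI67, the proliferation antigen, fell 7.15-fold, from 662 ± 29.6 to 92.6 ± 2.36 CPM, and TOP2A, a topoisomerase of dividing cells, fell 6.97-fold. Of 41 DNA replication and S-phase genes, 40 fell and 1 did not pass (41 fell adjusted over the list alone), with a median of -2.63. The replicative helicase subunits MCM4 and MCM3 fell 9.57-fold and 6.18-fold. The camera test, which compares a list with all other genes, gave an adjusted p = 6.49e-17 for mitosis and 7.77e-19 for replication, and both held with an estimated correlation (adjusted p = 0.0176 and 0.00023). Ranges of a list's p over alternatives below are those of the camera test. They include the fit against the controls of the other experiment and pool both directions.

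In total 14035 of 19006 genes (73.8%) passed an edgeR adjusted p of 0.05 between the KLF4 groups, 7108 higher and 6927 lower, and 8177 of them changed at least 2-fold (4441 higher, 3736 lower). Scaling by library size alone moved the median gene by -0.27 on the log2 scale and turned the split to 5781 higher and 8485 lower, so directions here are relative to the median gene. Protein-coding genes accounted for 6018 of the rises and 5603 of the falls.

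Among protein-coding genes at a mean of 5 CPM or more, those with the largest rises were at or near zero counts in the KLF4 controls. BGN, which encodes the matrix proteoglycan biglycan (chromosome X, 153494939 to 153509554), had 0 counts in the 3 controls and 295 ± 12.9 CPM with KLF4, at least 9450-fold higher against a floor of 3 counts over the group. The same floor gives at least 5430-fold for the alkaline phosphatase ALPG (170 ± 10.9 CPM), 5310-fold for the desmosome protein desmoplakin, DSP (166 ± 4.51 CPM), 3720-fold for LYPD2 (116 ± 9.62 CPM) and 2680-fold for the homeobox gene NKX6-2 (83.7 ± 6.45 CPM). The alpha-globin genes HBA2 and HBA1 went from 0 counts to 114 ± 9.04 and 107 ± 4.10 CPM, at least 3640-fold and 3440-fold higher. They are near-identical copies, so the division of reads between them is uncertain. Their log2 values against the NRBP2 controls, where both were present, were 3.67 and 4.6. IGFBP6, a secreted binding protein of insulin-like growth factors, went from 4 counts over the controls to 1207 ± 64.3 CPM. The edgeR adjusted p of these 8 genes lay between 1.6e-26 and 1.1e-13, and intervals and floors cover counting error only.

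The largest falls at that level included the progenitor and monocyte genes KIT, MS4A3, F13A1 and CCR2. KIT, the stem cell factor receptor (chromosome 4, 54657918 to 54740715), fell 36.3-fold, from 27.4 ± 2.30 to 0.757 ± 0.389 CPM, and VAT1L fell 36.0-fold. MS4A3, a marker of granulocyte and monocyte progenitors, fell 25.7-fold from 89.6 ± 3.01 to 3.48 ± 0.339 CPM. F13A1, the coagulation factor XIII subunit made by monocytes, fell 19.2-fold, SERPINB2, a plasminogen activator inhibitor, 18-fold, and CCR2, the monocyte chemokine receptor, 15.4-fold, from 253 ± 12.4 to 16.5 ± 1.52 CPM. DNAJC5B and PM20D2 fell 15-fold and 14.7-fold, and the edgeR adjusted p of these 8 genes lay between 3.9e-24 and 6.4e-17.

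Of 21 progenitor surface and primary granule genes, 15 fell and 5 rose (camera adjusted p = 0.00248, and 0.0347 with an estimated correlation). The granule protease CTSG fell 7.47-fold, from 677 ± 16.3 to 90.6 ± 3.03 CPM, while the interleukin-3 receptor chain IL3RA rose 4.42-fold. GATA2, a progenitor transcription factor, rose 3.65-fold against its own controls, and its sign turned against the NRBP2 controls (log2 -1.06), in which GATA2 stood at 151 ± 17.8 CPM. Of 26 genes of the MLL-fusion leukaemia programme, 15 fell and 6 rose (camera adjusted p = 0.0219). FLT3, a receptor kinase of leukaemic blasts, fell 7.48-fold and the survival gene BCL2 7.07-fold, from 335 ± 8.73 to 47.4 ± 0.643 CPM, while CPEB2 and PBX3 rose 3.02-fold and 1.83-fold. That call was lost with an estimated correlation (adjusted p = 0.166) and with the NRBP2 controls in place (adjusted p = 0.149, range over alternatives 0.00114 to 0.166). Of 34 MYC-regulated and ribosome biogenesis genes, 27 fell and 4 rose (27 and 5 adjusted over the list alone; camera adjusted p = 4.76e-05, 0.0138 with an estimated correlation). NCL, the nucleolar protein nucleolin, fell 2.64-fold and CAD, a pyrimidine synthesis enzyme, 3.64-fold, while the polyamine enzyme ODC1 rose 2.57-fold and the folate carrier SLC19A1 2.01-fold. Of 74 cytosolic ribosomal protein genes 66 fell and 5 rose, with a median of -0.61 (camera adjusted p = 5.18e-12, 0.059 with an estimated correlation). RPL5 and RPL27A each fell 1.86-fold, RPL36 rose 1.58-fold and RPL28 1.25-fold, the last not past the threshold when scaled by library size alone.

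The list of autophagy and lysosome genes rose, with 31 of 38 genes higher and 5 lower (camera adjusted p = 2.45e-06, and 0.0176 with an estimated correlation). MAP1LC3B, which coats autophagosomes, rose 14.7-fold, from 40.7 ± 1.65 to 599 ± 11.7 CPM, and the autophagy kinase ULK1 14.9-fold, while the lysosomal enzymes LIPA and GLA fell 1.98-fold and 1.84-fold. Of 42 interferon-stimulated genes 26 rose and 8 fell (camera adjusted p = 0.0118, 0.0428 with an estimated correlation), with ISG15 15-fold and IRF7 7.12-fold higher and HERC5 8.16-fold lower. Of 45 nuclear-encoded respiratory chain genes 37 rose and 3 fell, with a median of 0.61 (camera adjusted p = 2.45e-06, 0.059 with an estimated correlation). SDHA and UQCRC1 rose 2.95-fold and 2.55-fold, and ATP5MC1 and ATP5F1A fell 1.74-fold and 1.26-fold. Of 31 glycolysis and hypoxia-response genes 19 rose and 5 fell (camera adjusted p = 0.00233, 0.136 with an estimated correlation and 0.234 with the NRBP2 controls in place, range over alternatives 0.0002 to 0.234). NDRG1 rose 20.3-fold, from 66.9 ± 1.2 to 1357 ± 20.6 CPM, and the enolase ENO2 39.1-fold, while the pyruvate dehydrogenase kinases PDK3 and PDK1 fell 4.20-fold and 2.28-fold. Against the NRBP2 controls the log2 value of ENO2 was 0.51 instead of 5.29.

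Of 37 ATF4 and unfolded-protein-response genes 24 rose and 9 fell (camera adjusted p = 0.0241, 0.059 with an estimated correlation). The stress regulators NUPR1 and ATF5 rose 18.1-fold and 3.42-fold, and EDEM1 and VLDLR fell 3.06-fold and 2.80-fold. Scaled by library size alone the split was 14 to 11 and the list was not called (adjusted p = 0.223, range over alternatives 0.00326 to 0.223). Of 15 NRBP pseudokinase and TSC22-family partner genes 10 rose and 2 fell (camera adjusted p = 0.0185, 0.059 with an estimated correlation). NRBP2 led that list, its paralogue NRBP1 rose 1.98-fold, and STK39 and TSC22D1 fell 2.24-fold and 1.64-fold.

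Markers of other cell types were among the genes that rose. Of 9 epithelial and stromal markers with enough counts, 8 rose and 1 fell (camera adjusted p = 0.0185, 0.174 with an estimated correlation). The collagen gene COL1A1 went from 0.667 ± 0.264 to 218 ± 10.1 CPM, 327-fold higher, the tight junction gene CLDN7 rose 6.77-fold, and the cadherin CDH2 fell 3.97-fold. This call was lost with the NRBP2 controls in place (adjusted p = 0.0699) and when 1 CPM was required in 6 libraries (adjusted p = 0.157, range over alternatives 0.0013 to 0.174). Of 12 erythroid markers 4 rose and 0 fell (camera adjusted p = 0.122), of 6 T lymphocyte markers 4 rose and 1 fell (0.256), and of 6 B lymphocyte markers 1 rose and 3 fell (0.750). The erythroid list was called up when scaled by library size alone (0.042), with no low-count filter (0.0325) and in a fit of these 6 libraries alone (0.0158, range over alternatives 0.0158 to 0.241), and with the NRBP2 controls in place 4 members rose and 8 fell.

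Monocyte and macrophage genes moved in both directions, with 18 of 37 higher and 16 lower (camera adjusted p = 0.751). ITGAM, the integrin CD11b, rose 31.6-fold, from 44.8 ± 2.05 to 1416 ± 58.9 CPM, and the transcription factor CEBPB 26.9-fold, while the transcription factor IRF8 fell 6.59-fold, from 676 ± 6.77 to 103 ± 1.02 CPM, beside CCR2. Apoptosis-promoting genes were divided too, with 15 of 36 higher and 15 lower (camera adjusted p = 0.969). The pore-forming effector BAK1 rose 10.9-fold, from 57.8 ± 0.343 to 632 ± 18.2 CPM, and the kinase DAPK1 3.34-fold, while the apoptosome gene APAF1 fell 3.70-fold and PDCD4 3.29-fold. Over 20% of the exon length of PDCD4 and of ATF5 is shared with other genes, so their counts are uncertain. Of 17 apoptosis-restraining genes 8 were higher and 7 lower (camera adjusted p = 0.938), and of 33 p53 targets 16 were higher and 10 lower (0.335).

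No call was made for the other lists with the planned filter, scaling and preset correlation. Higher and lower members numbered 21 and 6 of 34 immediate early genes (camera adjusted p = 0.0871, and called up with no low-count filter at 0.0195, range over alternatives 0.0195 to 0.166), 15 and 9 of 24 NRF2 targets (0.335), 10 and 8 of 19 KLF and SP factors (0.178), and 8 and 9 of 23 genes of the KMT2 methyltransferase complexes (0.490). They numbered 10 and 11 of 28 NF-kB and cytokine genes (0.701), 7 and 5 of 16 MHC class II genes (0.701), 9 and 10 of 24 cholesterol synthesis genes (0.938) and 8 and 8 of 20 heat shock genes (0.681). Even splits depended on the scaling. With library size alone they were 5 and 14 for the KMT2 complexes, 7 and 14 for NF-kB and for cholesterol genes, and 4 and 12 for heat shock. With the NRBP2 controls in place the KMT2 complexes gave 4 and 15 (camera adjusted p = 0.113). Among lists that track RNA quality, 6 of 13 mitochondrially encoded messenger RNAs were higher and 1 lower (0.490), a split that became 1 and 6 when scaled by library size alone, and 3 of 17 replication-dependent histone genes were higher and 6 lower (0.490). In all, 13 of 30 lists were called, 7 up and 6 down, 6 of them also with an estimated correlation and 10 with the NRBP2 controls in place. For 25 of the 30 lists the numbers of higher and lower genes were the same adjusted over the list alone. The others were the replication and MYC lists, immediate early genes (21 and 7), cholesterol synthesis genes (10 and 10) and histone genes (3 and 4). The median, the mean and the direction of the test differed in sign for both apoptosis lists and for the NF-kB, cholesterol, heat shock and B lymphocyte lists.

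**Figure D2:**
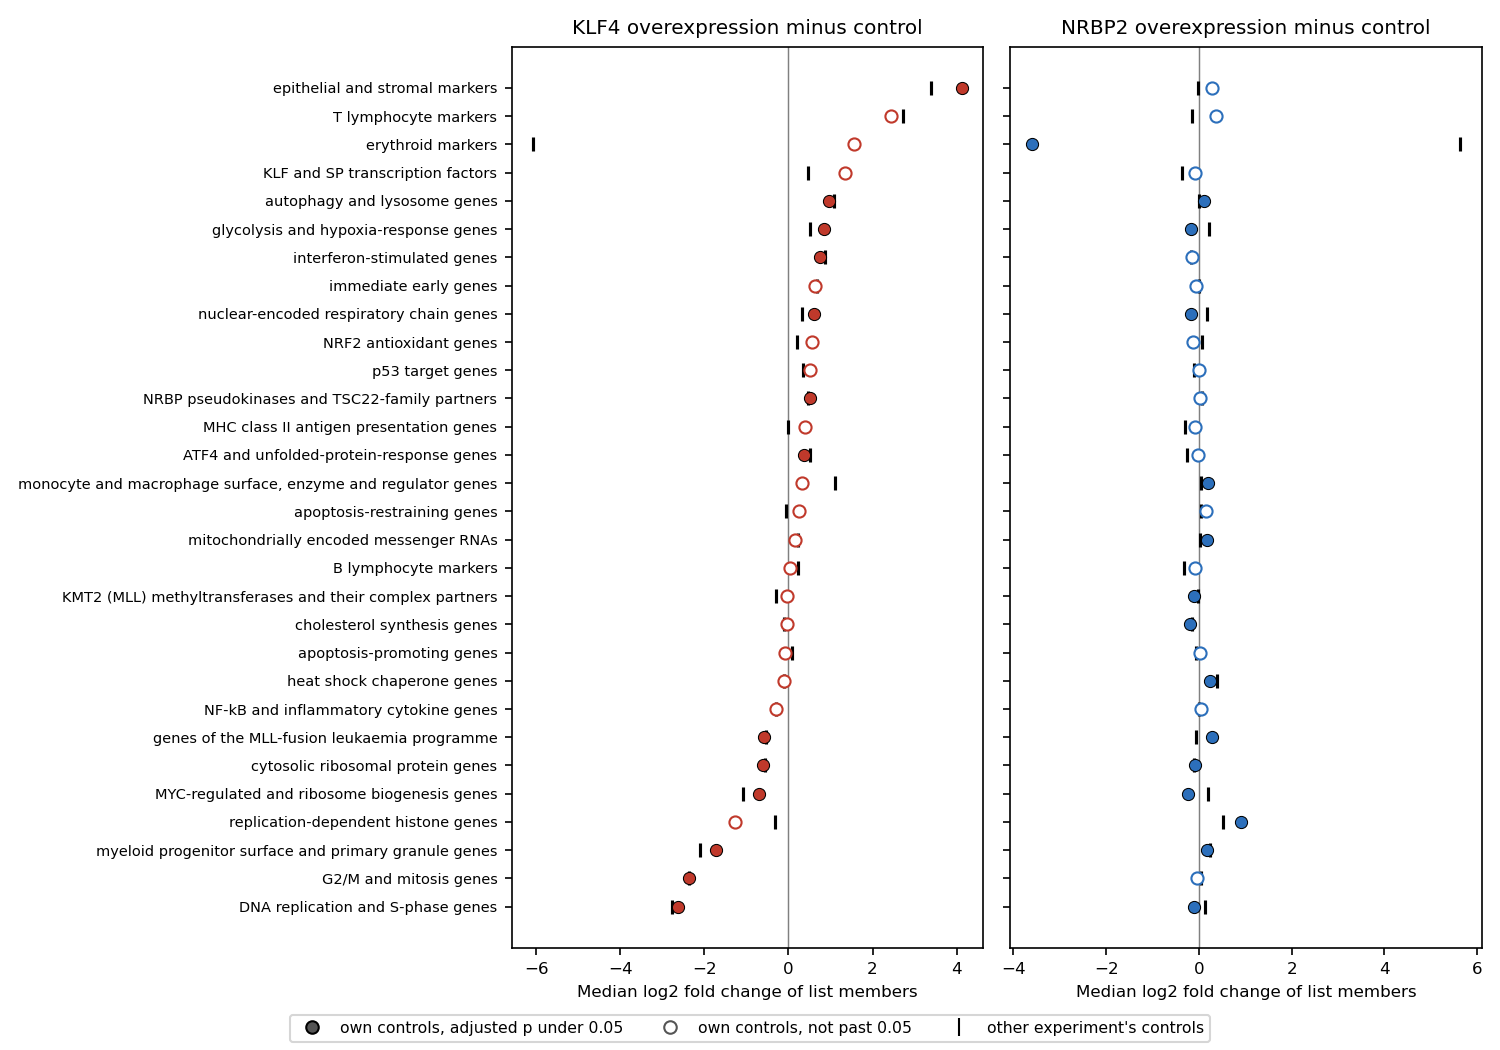
Median log2 fold change of the members of each of 30 gene lists, with KLF4 overexpression (left panel) and NRBP2 overexpression (right panel), each against its own controls. Filled circles passed the camera test at an adjusted p of 0.05, open circles did not, and black ticks give the median against the controls of the other experiment. DNA replication genes lie at -2.63 with KLF4, and erythroid markers with NRBP2 lie at -3.60 (-3.48 with members at 0 counts set to their bound) against the NRBP2 controls but at 5.64 against the KLF4 controls.

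Both control groups are labelled as control THP-1 cells, and they differed widely. Of 19006 genes, 7741 passed between the control sets, 4226 higher and 3515 lower in the NRBP2 controls, and 2105 differed at least 2-fold. FREM1 (123 ± 5.95 CPM) and RHAG, the Rh-associated glycoprotein of red cells (59.5 ± 2.10 CPM), had 0 counts in the KLF4 controls, which makes them at least 3950-fold and 1910-fold higher in the NRBP2 controls. NFIB, MYL4 and GCSAML, at 42.7 ± 5.32, 42.3 ± 3.03 and 34.6 ± 4.81 CPM, likewise had 0 counts in the KLF4 controls. Lower in the NRBP2 controls were SIGLEC1, a macrophage lectin (6.35-fold), the complement gene C3 (5.76-fold), KLF4, the homeobox gene SIX3 (5.10-fold) and the gelatinase MMP2 (4.75-fold). The edgeR adjusted p of these 10 genes lay between 1.4e-20 and 2.5e-11. Experiment and construct cannot be told apart in this comparison, since each experiment has its own controls.

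With 3 or fewer counts over the KLF4 controls and at least 5 CPM in the NRBP2 controls there were 96 genes, a set defined after the values were seen. Summed over the set, the NRBP2 controls held 1462, 1496 and 1484 CPM, the NRBP2 overexpression libraries 106.2, 103.3 and 108.4 CPM, the KLF4 controls 0.465, 0.659 and 0.443 CPM, and the KLF4 overexpression libraries 373.2, 413.3 and 384.5 CPM. All 96 genes were lower with NRBP2 overexpression, at a median of 7.2% of their level in the NRBP2 controls. Each list called in the NRBP2 comparison is therefore given with its value against the KLF4 controls, an alternative chosen after the data were examined.

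With NRBP2 overexpression heat shock chaperone genes were higher and cholesterol synthesis genes lower, by small amounts. Both directions were the same against the KLF4 controls, a comparison that uses the same 3 overexpression libraries, so the 2 are not independent. Of 20 heat shock genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.24 (camera adjusted p = 0.000199, 0.0169 with an estimated correlation). The inducible HSP70 gene HSPA1A rose 2.09-fold, from 8.18 ± 0.350 to 17.1 ± 0.562 CPM, and its co-chaperone BAG3 1.49-fold. FKBP4 and HSPA4 fell 1.52-fold and 1.2-fold, and both lay above the KLF4 controls. With the KLF4 controls in place 18 heat shock genes rose and 0 fell (adjusted p = 4.07e-12). Of 24 cholesterol synthesis genes 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 6.7e-05, 0.0169 with an estimated correlation), and 11 fell and 2 rose against the KLF4 controls (0.000766). Over alternatives the adjusted p ranged from 4.07e-12 to 0.0169 for heat shock and from 6.39e-07 to 0.0169 for cholesterol synthesis.

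Between the NRBP2 groups 5315 of 19006 genes (28.0%) passed an edgeR adjusted p of 0.05, 2194 higher and 3121 lower, and 1506 changed at least 2-fold, 220 higher and 1286 lower. With the KLF4 controls in place 5742 passed and the majority turned, with 3043 higher and 2699 lower. Without the genes at 3 or fewer counts over the KLF4 controls 4953 passed, 2191 higher and 2762 lower. That filter left 18230 genes, among them genes with more counts there that differ between the control sets. Against both sets of controls 1347 genes passed in the same direction, 676 higher and 671 lower, of which 42 and 119 changed at least 2-fold. Another 1143 of the 5315 passed in opposite directions. Both comparisons share the overexpression libraries, and the number that such sharing gives with no effect of NRBP2 was not computed.

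Among protein-coding genes at a mean of 5 CPM or more, the 8 that fell furthest had 0 to 22 counts over the 3 KLF4 controls. ANGPT1, which encodes the vessel growth factor angiopoietin 1 (chromosome 8, 107249482 to 107498055), fell 23.9-fold, from 19.3 ± 3.33 to 0.805 ± 0.180 CPM, and had 0 counts in the KLF4 controls. SPARC and COL25A1 each fell 22.6-fold, COL2A1 21-fold, the tetraspanin CD9 20.8-fold, DLC1 19.2-fold, the platelet adhesion gene SELP 19.1-fold and the cancer-testis gene MAGEA3 18.3-fold. Each of these 8 genes was higher with NRBP2 overexpression than in the KLF4 controls, the reverse direction, by the fitted values. Their edgeR adjusted p lay between 1.3e-17 and 3.7e-11 against the NRBP2 controls.

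Apart from NRBP2 itself, the largest rises among protein-coding genes at a mean of 5 CPM or more were MMP2 (4.88-fold, from 2.60 ± 0.818 to 12.7 ± 0.779 CPM), ALOX5, the arachidonate 5-lipoxygenase (4.79-fold), CEACAM6 (3.57-fold), C3 (3.19-fold), NPTXR (2.84-fold), SERINC2 (2.57-fold) and the calcium-binding S100A9 (2.57-fold, from 23.6 ± 0.826 to 60.6 ± 5.18 CPM). Their edgeR adjusted p lay between 7.1e-15 and 2.2e-09. Against the KLF4 controls ALOX5, CEACAM6, NPTXR, SERINC2 and S100A9 also rose (log2 0.71, 0.50, 0.95, 0.89 and 0.21), MMP2 did not pass (0.04) and C3 fell (-0.85).

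A further 16 genes, chosen after their values were seen, had the largest changes, by the smaller of the 2 log2 values, in 1 direction against both sets of controls, among protein-coding genes at a mean of 5 CPM or more over these 9 libraries with the overexpression libraries beyond all controls. NRBP2 led the rises, followed by ITGB7, MDGA1, NPTX2, RNASE3, IER5L, KLHL35 and PAX5, all 2.13-fold to 2.57-fold higher than in the NRBP2 controls. RNASE3, an eosinophil granule ribonuclease, went from 4.68 ± 1.10 to 10.9 ± 1.17 CPM and PAX5, a B-cell transcription factor, from 4.14 ± 0.420 to 10.6 ± 0.743 CPM. The falls were RASGRP4 (4.79-fold, from 13.2 ± 0.253 to 2.76 ± 0.324 CPM), the synaptic vesicle gene SV2A (13.6-fold), PON2 (4.33-fold), the ubiquitin ligase TRIM32 (4.21-fold), TNFRSF25 (9.09-fold), SIX3 (3.69-fold), TBL1X (2.87-fold) and the cholesterol exporter ABCA1 (2.53-fold). ABCA1 stood at 52.2 ± 2.33 CPM in the KLF4 controls, 22.8 ± 1.10 CPM in the NRBP2 controls and 9.02 ± 1.3 CPM with NRBP2 overexpression. More than 20% of the exon length of ITGB7 and IER5L is shared with other genes, so their counts are uncertain.

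Monocyte and macrophage genes rose against the NRBP2 controls, with 17 of 37 higher and 3 lower (18 and 3 adjusted over the list alone), a median of 0.20 (camera adjusted p = 0.000199, 0.0253 with an estimated correlation). The calprotectin genes S100A9 and S100A8 each rose 2.57-fold, while LYZ, the lysozyme gene, and VCAN fell 1.57-fold and 1.60-fold. From the KLF4 controls the median was 0.04, with 7 higher and 12 lower (adjusted p = 0.148, range over alternatives 4.39e-06 to 0.148). Of 21 progenitor and granule genes 9 rose and 4 fell (9 and 5 adjusted over the list alone), with a median of 0.17 and a mean of -0.05 (camera adjusted p = 0.0434, 0.0973 with an estimated correlation). CTSG and RNASE2 rose 1.47-fold and 1.71-fold, while GATA2 and PRSS57 fell 3.72-fold and 3.33-fold. Measured from the KLF4 controls 12 rose and 4 fell (0.0136). That list was not called without replicate 1 (adjusted p = 0.0608) or replicate 3 (0.0575) of the NRBP2 controls, without replicate 3 of the overexpression libraries (0.0605) or in a fit of these 6 libraries alone (0.0527), in a range over alternatives of 0.00661 to 0.0973. Of 26 genes of the MLL-fusion programme 11 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.00603, 0.0973 with an estimated correlation). PBX3 and HOXA9 rose 1.35-fold and 1.49-fold, FLT3 fell 1.2-fold, and the homeobox gene MEIS1 fell 15.7-fold from 8.69 ± 1.25 CPM, with 0 counts in the KLF4 controls. Set against the KLF4 controls 5 rose and 10 fell (0.234, range over alternatives 0.000202 to 0.234).

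Several lists moved against the NRBP2 controls and in the opposite direction against the KLF4 controls. Of 34 MYC-regulated and ribosome biogenesis genes 19 fell and 0 rose (20 and 0 adjusted over the list alone; camera adjusted p = 3.04e-07, 0.00364 with an estimated correlation), with RCL1 2.38-fold and NPM1 1.32-fold lower, and 23 rose and 1 fell against the KLF4 controls (3.95e-07). Of 41 replication genes 15 fell and 0 rose (16 and 0 adjusted over the list alone; 0.00499, 0.0408 with an estimated correlation), among them CLSPN (1.29-fold) and CDC25A (1.3-fold), and 14 rose and 0 fell against the KLF4 controls (0.00157). Of 31 glycolysis and hypoxia genes 18 fell and 3 rose (19 and 3 adjusted over the list alone; 0.000152, 0.0699 with an estimated correlation), and 16 rose and 3 fell against the KLF4 controls (0.000115). ENO2 and PFKM fell 7.34-fold and 7.29-fold, while the glucose transporter SLC2A1 rose 1.55-fold and PGAM1 1.15-fold. Of 45 respiratory chain genes 22 fell and 0 rose (23 and 1 adjusted over the list alone; 0.000199, 0.0973 with an estimated correlation), with ATP5F1B and ATP5PO 1.29-fold and 1.64-fold lower, and 27 rose and 0 fell against the KLF4 controls (1.85e-09). Of 12 erythroid markers 11 fell and 0 rose, both counts the same adjusted over the list alone (8.56e-08, 0.00364 with an estimated correlation). GATA1, the erythroid transcription factor, fell 12.1-fold, from 43.1 ± 3.6 to 3.56 ± 0.157 CPM, against 0.105 ± 0.0661 CPM in the KLF4 controls, and HBA2 fell 12.2-fold. Against the KLF4 controls 7 erythroid markers rose and 0 fell (1.03e-06). Over alternatives, with the reversed calls against the KLF4 controls included, the adjusted p ranged from 8.12e-10 to 0.00364 (MYC), 0.00117 to 0.0408 (replication), 5.42e-06 to 0.0699 (glycolysis), 1.85e-09 to 0.0973 (respiratory chain) and 7.33e-11 to 0.00364 (erythroid). The lowest value for the respiratory chain is that of its reversed call.

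Of 74 ribosomal protein genes 27 fell and 3 rose, both counts the same adjusted over the list alone (camera adjusted p = 0.000199, 0.218 with an estimated correlation), with RPS26 and RPS12 1.32-fold and 1.18-fold lower and RPS23 and RPL37 1.14-fold and 1.12-fold higher, and 36 fell and 2 rose against the KLF4 controls (2.53e-07). RPL37 did not pass without replicate 1 of the NRBP2 controls (edgeR adjusted p = 0.0945). Of 23 genes of the KMT2 complexes 8 fell and 0 rose, the same adjusted over the list alone (0.00603, 0.0427 with an estimated correlation). PSIP1, the chromatin tether LEDGF, fell 1.84-fold and the demethylase KDM6A 12.4-fold, from 6.61 ± 0.360 CPM against 2 counts over the KLF4 controls, and 5 members fell and 3 rose against those controls (0.835). Of 38 autophagy and lysosome genes 12 rose and 3 fell (13 and 6 adjusted over the list alone; 0.00404, 0.0699 with an estimated correlation), with CTSZ 1.45-fold higher and WIPI1 and ATG12 2.24-fold and 1.3-fold lower, and 8 rose and 10 fell against the KLF4 controls (0.835). Of 13 mitochondrially encoded messenger RNAs 4 rose and 0 fell (5 and 0 adjusted over the list alone; 0.00200, 0.381 with an estimated correlation), MT-ATP8 by 1.54-fold and MT-ND6 by 1.19-fold. Of 17 replication-dependent histone genes 6 rose and 0 fell (7 and 0 adjusted over the list alone; 0.00240, 0.0358 with an estimated correlation), HIST2H2BE 2.99-fold and HIST1H2AC 2.48-fold. The last pair of lists, which track RNA quality, was not called against the KLF4 controls (0.672 and 0.157). Over alternatives the adjusted p ranged from 2.53e-07 to 0.218 (ribosomal proteins), 0.00144 to 0.835 (KMT2 complexes), 0.000113 to 0.835 (autophagy), 1.39e-05 to 0.672 (mitochondrial) and 0.000916 to 0.157 (histones).

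Apoptosis-promoting genes were not called with NRBP2 overexpression, with 5 of 36 higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.856). BIK and BAK1, which promote apoptosis at the mitochondrion, rose 1.40-fold and 1.19-fold, while DAPK1 and the nuclease DFFB fell 1.78-fold and 1.58-fold. Of 17 apoptosis-restraining genes 7 were higher and 2 lower (0.124), a list that was called without replicate 3 of the NRBP2 controls (0.0486) and with no low-count filter (0.0188, range over alternatives 0.0188 to 0.964), and of 33 p53 targets 7 were higher and 8 lower (0.919). Higher and lower members numbered 2 and 8 of 35 mitosis genes (0.440), 4 and 10 of 42 interferon-stimulated genes (0.232), 6 and 6 of 28 NF-kB and cytokine genes (0.840), 1 and 6 of 16 MHC class II genes (0.325), and 8 and 8 of 37 ATF4 and unfolded-protein-response genes (0.988). The last list was called down against the KLF4 controls (0.000336, range over alternatives 0.000336 to 1). They numbered 5 and 10 of 34 immediate early genes (0.472), 3 and 6 of 24 NRF2 targets (0.126), 0 and 3 of 19 KLF and SP factors (0.300, and called down at 9.26e-05 against the KLF4 controls, range over alternatives 9.26e-05 to 0.404), and 2 and 2 of 15 NRBP and TSC22-family genes (0.232, and called up with no low-count filter at 0.044, range over alternatives 0.044 to 0.314). Of the other cell types, T lymphocyte markers gave 0 and 1 of 6 (0.469), B lymphocyte markers 2 and 1 of 6 (0.560), and epithelial and stromal markers 1 and 2 of 9 (0.983). In all, 15 of 30 lists were called, 7 up and 8 down, 8 of them also with an estimated correlation. Against the KLF4 controls 4 of the 15 were called in the same direction and 5 in the opposite one. For 8 of the 30 lists the numbers of higher and lower genes were the same adjusted over the list alone. Among lists not called, the latter gave 8 and 2 for apoptosis-restraining genes, 9 and 8 for p53 targets, 2 and 6 for MHC class II, 10 and 9 for ATF4 targets, 6 and 10 for immediate early genes, 3 and 8 for NRF2 targets, 3 and 2 for the NRBP list, 0 and 0 for T lymphocyte markers and 3 and 2 for epithelial markers. The median, the mean and the direction of the test differed in sign for the progenitor, apoptosis-promoting, NF-kB, ATF4, T lymphocyte, B lymphocyte and epithelial lists. Of the named members, LYZ, VCAN, GATA2, PBX3, CDC25A, RCL1, NPM1, ENO2, ATP5F1B, ATP5PO, MT-ND6, RPS26, FKBP4, HSPA4, WIPI1, MEIS1, KDM6A, GATA1 and HBA2 had the opposite sign against the KLF4 controls. Over 20% of the exon length of LYZ, HOXA9, ATP5PO, MT-ATP8 and WIPI1 is shared with other genes, so their counts are uncertain.

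**Figure D3:**
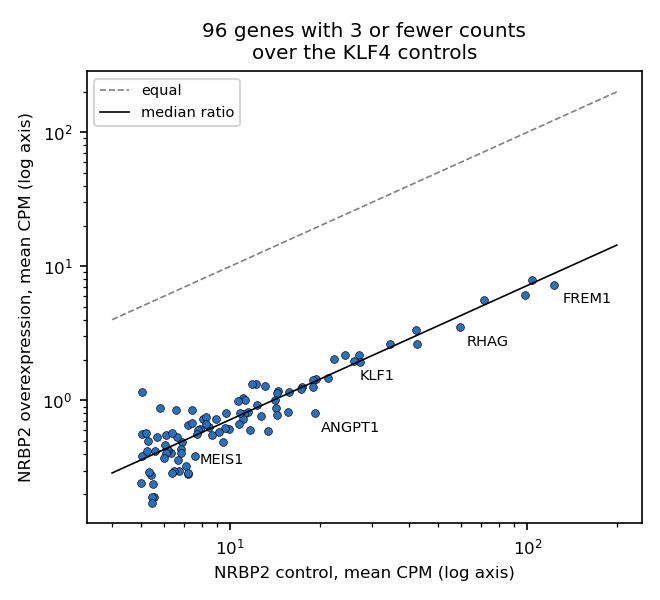
Mean CPM in the 3 NRBP2 overexpression libraries against mean CPM in the 3 NRBP2 controls, both on log axes, for the 96 genes with 3 or fewer counts over the KLF4 controls and at least 5 CPM in the NRBP2 controls. Each point is 1 gene, the dashed line marks equal levels, and the solid line the median ratio of 7.2%.

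Against their own controls, some genes moved the same way with KLF4 and with NRBP2 overexpression, and more moved in opposite directions. ALOX5 rose with both, 7.35-fold with KLF4 (from 6.30 ± 1.2 to 46.3 ± 1.28 CPM) and 4.79-fold with NRBP2. The homeobox gene DLX3 (20.1-fold and 8.84-fold) and ENHO (50.9-fold and 5.83-fold) rose with both against their own controls, as did NRBP2. Over 20% of ENHO's exon length is shared with other genes, so its counts are uncertain. SLC8A2 rose 510-fold with KLF4, and its rise with NRBP2, at least 2.1-fold, rests on 7 counts against 0 and did not pass without replicate 1, 2 or 3 of the NRBP2 controls or replicate 2 or 3 of the overexpression libraries (edgeR adjusted p = 0.0622 to 0.138). SV2A fell 6.98-fold with KLF4 and 13.6-fold with NRBP2, CNRIP1 7.49-fold and 7.76-fold, the thrombin receptor F2R 8.46-fold and 6.57-fold, and ST8SIA6 8.34-fold and 14-fold. PLCH1 went from 26 counts to 1 with KLF4, a ratio of 0.0481 (95% counting interval 0.00117 to 0.293), and fell 12.4-fold with NRBP2. Against the KLF4 controls the NRBP2 changes of SLC8A2, DLX3, PLCH1, ST8SIA6, CNRIP1 and F2R had the opposite sign.

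Of the genes tested, 809 rose with both, where 820.5 would be shared by independent lists (odds ratio 0.975, Fisher's exact p = 0.606). Fewer fell with both than independent lists would share, 1002 against 1137.5 (odds ratio 0.795, Fisher's exact p = 3.09e-08). The opposite directions were in excess, with 1374 genes up with KLF4 and down with NRBP2 (odds ratio 1.392, Fisher's exact p = 1.16e-16) and 1052 down with KLF4 and up with NRBP2 (odds ratio 1.715, Fisher's exact p = 9.56e-32). TRIM29, VWA1 and LCN15 rose with KLF4 and fell with NRBP2, while CEACAM6, NPTXR and PAX5 did the reverse (9.16-fold, 4.32-fold and 4.19-fold lower with KLF4). TRIM29 and LCN15, with 21 and 11 counts over the NRBP2 controls and 0 with NRBP2 overexpression, had 0 counts in the KLF4 controls too. Across genes the log2 changes had a Spearman rho of -0.10. Genes are not independent replicates, so rho and the Fisher p values describe the overlap of these calls and are not a test over replicates. The controls of the 2 comparisons are separate libraries, and 7741 genes passed between them. Of the 5315 NRBP2 calls, 1143 passed with the opposite sign against the KLF4 controls, 818 of them falls. A gene low in the KLF4 controls and high in the NRBP2 controls can rise with KLF4 and fall with NRBP2 through that difference alone. The excess of opposite directions can therefore come from the control sets and does not show that KLF4 and NRBP2 act in opposite ways. Shared rises exceeded those of independent lists among changes of at least 2-fold (91 against 51.4, odds ratio 2.341, Fisher's exact p = 2.71e-09), with no low-count filter (odds ratio 2.269) and with DESeq2 (1.283). Shared falls did so with no low-count filter (1.883), and with DESeq2 gave an odds ratio of 1.024. The opposite directions had larger odds ratios in both settings, 3.196 and 4.322 with no filter and 1.745 and 2.105 with DESeq2. Without the filter the background grew to 36555 genes. At 2-fold the opposite directions gave 2.637 and 1.727.

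The test of the difference between the 2 effects passed for 12657 genes, 6420 with the higher log2 change under KLF4 and 6237 with the higher one under NRBP2. Scaled by library size alone the split was 5221 and 7635. KMT2C responded more to KLF4 than to NRBP2, by 0.77 on the log2 scale with TMM scaling. VAT1L (-6.48, SE 0.157), KIT (-5.35, SE 0.228), UGT3A2 (-5.06, SE 0.307), CEACAM6 (-5.02, SE 0.250) and SLC6A11 (-5.02, SE 0.298) differed most in the negative direction among genes at a mean of 5 CPM or more. UGT3A2 fell from 8.36 ± 0.893 to 0.369 ± 0.256 CPM with KLF4 and stood at 9.77 ± 0.913 and 14.4 ± 0.584 CPM in the NRBP2 controls and overexpression libraries. In the positive direction the naming rule gave DSP, TRIM29, HBA2, LCN15 and KCNJ12 by fitted values, all with 0 counts in the KLF4 controls, so their sizes and order are not determined. KCNJ12, a potassium channel gene, reached 26.2 ± 3.50 CPM with KLF4 and stood at 4.38 ± 0.314 and 0.146 ± 0.0617 CPM in the NRBP2 controls and overexpression libraries. The edgeR adjusted p of these 10 genes lay between 3.2e-22 and 4.8e-10.

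**Figure D4:**
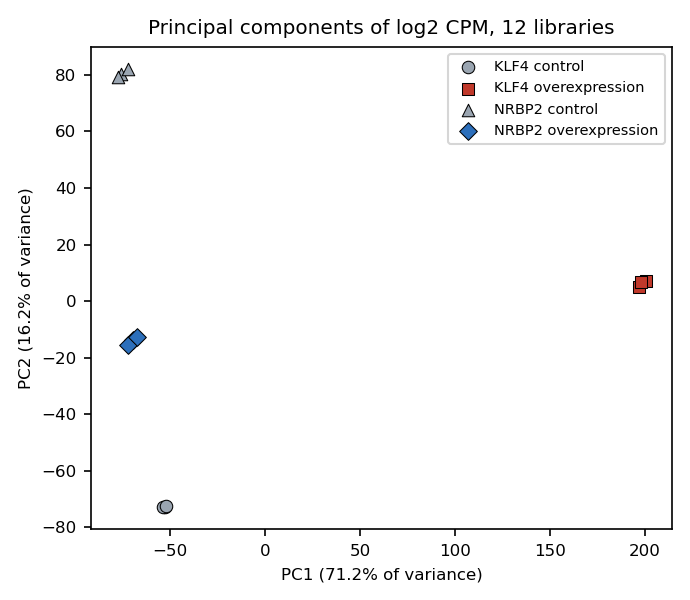
First and second principal components of log2 CPM over 12 libraries, holding 71.2% and 16.2% of the variance, with 1 point per library. The first component separates the KLF4 overexpression libraries from the other 9, and the second separates the KLF4 controls from the NRBP2 controls, with the NRBP2 overexpression libraries between them.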

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

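The test of the difference between effects was planned, while the bounds set for the counts over other splits of the libraries were written only after those counts had been seen.

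The difference between the KLF4 and NRBP2 effects is listed here because its own test passed for 12657 genes, so the 2 experiments moved many genes by different amounts or in different directions. On the log2 scale, KLF4 minus NRBP2 experiment, the value was 5.95 for KLF4, -3.74 for NRBP2 and 0.77 for KMT2C. The lowest values among named genes were VAT1L (-6.48), KIT (-5.35), UGT3A2 (-5.06), CEACAM6 (-5.02) and SLC6A11 (-5.02). The highest fitted values among named genes were DSP (19.27), TRIM29 (18.78), HBA2 (18.43), LCN15 (18.34) and KCNJ12 (17.59). All 5 have 0 counts in the KLF4 controls, so their fitted values depend on the prior count, are no bound and give no order. Each effect is measured from its own controls, and 7741 genes passed between the 2 sets of controls, so the difference of effects holds the difference of controls too.

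For the difference, 1 of 100 splits, the real one, gave 12657 genes or more. That rank does not exclude chance, since the count follows the KLF4 labels, which alone make 10 splits. The highest other split gave 12199 genes and reverses the labels within the NRBP2 experiment alone, and the splits drawn that keep the KLF4 labels and mix the NRBP2 labels gave 10416 to 10792. The KLF4 labels alone thus give a count nearly as large, and the count of splits does not show that the 2 effects differ. The 6 libraries of a single comparison make 10 splits, too few for a share under 0.05. Of these, 1 of 10 reached the real value for the KLF4 comparison (14035 genes, highest other 0), 1 of 10 for the NRBP2 comparison (5315, highest other 0) and 1 of 10 for the controls (7741, highest other 0).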

How the results depend on the processing

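The controls of the other experiment, and counts without the genes near 0 in the KLF4 controls, were chosen as alternatives only after the data were examined, and the other settings were planned. With 1 library left out the number of genes past the threshold ran from 13633 to 13760 for KLF4, 4369 to 5395 for NRBP2, 12318 to 12538 for the difference and 6789 to 7590 for the controls, and called lists from 13 to 13 and from 14 to 15. In the same runs the log2 change of KLF4 was 5.761 to 5.839 in the KLF4 comparison and -0.237 to -0.069 in the NRBP2 comparison, KMT2C 0.62 to 0.672 and -0.135 to -0.067, and NRBP2 4.732 to 4.87 and 8.501 to 8.596. A 2-fold threshold gave 8177, 1506, 7832 and 2105 genes, fewer by construction. Replicate number as a block gave 13544, 4220 and 12041, and 7119 for the controls in a fit of the 6 control libraries alone (7445 there without the block), and libraries of the same number correlated at -0.037 to 0.011, so the numbers do not pair samples. The block ended the call of the progenitor list with NRBP2 (adjusted p = 0.0646, range over camera alternatives 0.00661 to 0.0973). An estimated correlation called 6 and 8 lists, fry, which does not compare a list with other genes, 28 and 23. By fry the apoptosis-promoting list (adjusted p = 0.00404) and the apoptosis-restraining list (2.29e-05) turned direction with KLF4, and p53 targets (0.00398) and ATF4 targets (0.037) did with NRBP2, whose members move both ways. The odds ratio of genes that rose with both was 2.341 at 2-fold, 2.269 with no low-count filter, 1.283 with DESeq2 and 0.677 with the controls exchanged, and that of genes that fell with both 1.883 with no filter and 1.024 with DESeq2. Those of the opposite directions were 2.637 and 1.727 at 2-fold, 3.196 and 4.322 with no filter and 1.745 and 2.105 with DESeq2. GATA2 with KLF4 turned to -1.06 from the NRBP2 controls. From the KLF4 controls the NRBP2 comparison gave log2 values of -2.52 for KLF4, -0.44 for KMT2C, -0.85 for C3, 7.69 for ANGPT1, 1.41 for SPARC, 4.09 for COL25A1, 5.83 for COL2A1, 2.16 for CD9, 7.275 for SELP, 5.05 for DLC1 and 7.64 for MAGEA3. LYZ gave 0.19, VCAN 0.10, GATA2 1.03, PBX3 -0.15, MEIS1 7.16, KDM6A 4.44, CDC25A 0.30, RCL1 0.19, NPM1 0.20, ENO2 1.90, ATP5F1B 0.18, ATP5PO 0.18, MT-ND6 -0.11, RPS26 0.26, FKBP4 0.50, HSPA4 0.22 and WIPI1 0.11. GATA1 gave 5.04, HBA2 7.54, SLC8A2 -1.51, DLX3 -0.71, PLCH1 2.93, ST8SIA6 2.02, CNRIP1 0.18 and F2R 0.04, fitted values that are no bound where a group has 0 counts. The lists that turned and passed from at least 1 set of controls had an adjusted p of 0.148 (monocyte), 0.234 (MLL programme), 0.00157 (replication), 3.95e-07 (MYC), 0.000336 (ATF4), 0.000115 (glycolysis), 1.85e-09 (respiratory chain), 0.835 (autophagy) and 1.03e-06 (erythroid). The cause of these changes and reversals was not tested except as given below under other observations. Of values other than the answers to a comparison, 1908 stayed the same under planned settings, 22 became weaker, 26 stronger and 4 reversed. With 1 library left out 1550 stayed the same, 9 became weaker and 1 stronger, and under added settings 166 stayed the same, 19 became weaker, 1 stronger and 44 reversed. Depth limits the genes near the floor, such as SLC8A2.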

Other observations

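The tests of the 96 genes of the NRBP2 controls, of sequencing depth and of the NRBP2 transcript were chosen only after the values they use had been seen, while those of olfactory receptor genes and of other cells in the KLF4 overexpression libraries were set before their results.

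The 96 genes present in the NRBP2 controls and near 0 in the KLF4 controls fell by nearly 1 shared ratio, with an interquartile range of 0.44 on the log2 scale (quartiles -4.06 and -3.62). A swap of single libraries is argued against, since 0 of 12 libraries correlated best with another group. That test cannot see a swap of all libraries of a group. The NRBP2 overexpression libraries correlated at 0.974 to 0.975 with the KLF4 controls and at 0.965 to 0.966 with the NRBP2 controls. NRBP2 stood at 13.2 ± 1.19 CPM in the KLF4 controls and 12.1 ± 0.707 CPM in the NRBP2 controls. Its level alone is thus argued against as the source of the difference between the control sets. Among erythroid markers, a list fixed before the data were examined, 9 reached 1 CPM in the NRBP2 controls. Of these, 7 had 3 or fewer counts in the KLF4 controls. Whether NRBP2 lowered the 96 genes in the overexpression libraries stays open. A small share of other cells in the NRBP2 controls, present at 7.2% of that level with NRBP2 overexpression, may account for the pattern. Such cells would have to bring no reads of MTAP, CDKN2A or CDKN2B, chosen after their values were seen, which had 0 counts in all 12 libraries. The erythroid marker HBA2 (12.2-fold lower) is among the 96 genes. Outside the set, the erythroid marker GATA1, with 10 counts over the KLF4 controls, went from 43.1 to 3.56 CPM. The megakaryocyte gene ITGA2B, also outside the set and chosen after its values were seen, had 298 counts over the KLF4 controls. It went from 299 ± 22.7 to 24.7 CPM. Of the 12 erythroid markers tested EPOR is also expressed in the KLF4 controls, and the labels name no sort that would remove such cells. An effect of NRBP2 on these genes or on such cells, and RNA or reads of another library, remain open, and no test separates them.

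Transcripts near 0 in the KLF4 controls reached 1 CPM with KLF4 overexpression for 340 genes, 265 of them protein coding, against 0 genes in the NRBP2 comparison, while 5 went the other way. Depth is argued against by a ratio of mean totals of 0.97. Genomic DNA or transcription leaking over all silent genes is argued against by olfactory receptor genes, of which 0 of 365 reached 1 CPM against 265 of 4585 other silent protein-coding genes (odds ratio 0, upper 95% limit 0.167, Fisher's exact p = 1.5e-09). The other cells of the NRBP2 controls are argued against by an interquartile range of 4.47 between KLF4 overexpression and NRBP2 control levels of their 96 genes. Activation by KLF4 at selected genes may explain the pattern, as a hypothesis found on these data and not tested, and a change of cell state, direct or not, cannot be separated from it here.

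The rise of the NRBP2 transcript with KLF4 overexpression had 3 explanations tested. The scaling between libraries is argued against by a log2 change of 4.53 with library size alone. Carry-over from the NRBP2 overexpression libraries would need a share of 7.86%, which would leave no gene below that share of its level there. It is argued against as the only source by 8 of 7451 genes of 20 CPM or more there, MS4A3 at 1.64% among them. These genes lay below that share in the KLF4 overexpression libraries. The noncoding transcript AC234917.1 at the 3' end of NRBP2 (chromosome 8, 143833270 to 143834063), chosen after its values were seen, summed to 148 counts in the KLF4 overexpression libraries, 1 in their controls and 2 with NRBP2 overexpression, which may reflect transcription at the NRBP2 locus itself. Its neighbour PUF60, also chosen after its values were seen, rose from 251 ± 4.54 to 533 ± 16 CPM, and whether KLF4 acts on NRBP2 directly was not tested.

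A further test was set before its result and left out of the patterns above after its result was seen. It compared the KLF4 controls with the NRBP2 overexpression libraries over the genes called with KLF4 overexpression against the NRBP2 controls. The median log2 difference was 0.04 for 7019 higher genes and -0.07 for 7415 lower genes. The difference between them was 0.11, where 0.1 had been set as the bound for KLF4 made from the construct in the KLF4 controls. The bound was met, but experiment and construct cannot be told apart here, so no cause is concluded.

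MTAP, CDKN2A and CDKN2B (chromosome 9, 21802543 to 22009363), chosen after their values were seen, had 0 counts in all 12 libraries. MEIS1 had 0 counts in the KLF4 controls, 850 in the NRBP2 controls, 62 with NRBP2 overexpression and 0 with KLF4 overexpression, and KDM6A had 2, 647, 59 and 18.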
